A study of Homo sapiens with 5 samples.

How the data were processed

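RNA was measured in TOV21G, an established human ovarian clear cell carcinoma cell line. Total RNA was isolated with Trizol and libraries were made with a stranded total RNA kit, per the labels' protocols. Total RNA libraries keep transcripts without a poly(A) tail, such as histone mRNAs and small structured RNAs. The series holds 5 libraries, 1 per treatment. The labels put shControl (control replicate 1, shRNA experiment) and the vehicle (control replicate 2, drug experiment) in the control group, and shHDAC6, ACY1215 and CAY10603 in the repressed HDAC6 group as replicates 1, 2 and 3. The replicate numbers follow the order of the records and only name the libraries. The 3 interventions are different treatments, and nothing says that the libraries came from repeated cultures. The p-values of single genes therefore measure only the spread between these libraries.

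The deposited table holds expected counts per gene as whole numbers, named count per the file headers. RSEM 1.2.3, edgeR (no version given) and the hg19 build are named in the submitters' processing notes, which give no role for each tool. The same table holds FPKM values made by the authors, per the file headers, with 2 decimals. The aligner, the annotation version, the read length and the strand setting are not given in the sources used here. The column headed DMSO was read as the vehicle library, because DMSO is a solvent used as a vehicle and the labels hold 1 vehicle sample. Columns of unknown samples numbered 0. The table has 28442 gene rows and 2 blank rows, which were left out. Symbols of 27 rows had turned into dates and were not named. The genome annotation at hand is of another build, so no coordinates are given. Genes of the mitochondrial genome are represented by 0 rows of a list of 15, so that list was not analysed here.

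Total counts were 57442767, 43498805, 51563718, 54620960 and 48776359 for shControl, vehicle, shHDAC6, ACY1215 and CAY10603. At such depth counting error is small for most genes above the floor of 5 CPM, a count scaled to the size of its library, used for single pairs. Intervals given at a confidence level of 95% cover counting error only, and not the spread between cultures. They are exact Poisson intervals for single libraries and exact binomial intervals for ratios of 2 libraries.

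Counts were used as deposited, with no further rounding needed. For repressed HDAC6 against control, edgeR 4.0.16 in R 4.3.3 was used with TMM normalization, a robust quasi-likelihood F test and experiment type (shRNA or drug) as a covariate. Genes with at least 1 CPM in at least 2 libraries were tested (13449 genes), with 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Gene lists written before the data were examined were tested with camera of limma 3.58.1, for lists with at least 5 tested members. The correlation between list genes was preset at 0.01, and the test was repeated with an estimated correlation. Camera ranks the genes of a list against the other genes, and at 0.01 it treats them as nearly independent. Those p-values are not a measure of the spread between libraries. On simulated data for this comparison, 13295 genes were tested at the fitted dispersion, with the same planted fold in every intervention. There 71% of the genes changed 2-fold and 100% of those changed 4-fold were recovered, with 7 false calls. Genes whose folds differ between the interventions have more spread in the fit, so these shares do not apply to them.

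Single pairs have 1 library on each side, so they carry no test and no replicate check. Their log2 folds are of TMM-scaled CPM with a prior count of 2, for 10741 genes with a mean of at least 5 CPM over the 5 libraries. Genes at or past 2-fold were counted. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 50 bins, and that percentile describes these libraries only. A fold against a library with 0 counts was computed against 3 counts in that library and is a lower bound. That bound covers counting error only, and not the split of reads between similar rows. Both drugs were set against the same vehicle library, so the correlation of their folds was simulated 20 times for unchanged libraries.

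The lists covered the HDAC family, SWI/SNF subunits, p53 targets, pro- and anti-apoptotic genes, G2 and M phase, DNA replication, heat shock, unfolded protein response, NRF2 targets, interferon-stimulated genes, cholesterol synthesis, tubulins, cilium, replication-dependent histones, genes raised by broad deacetylase inhibitors, epithelial and mesenchymal genes, clear cell carcinoma markers, NF-kappaB and chemokine genes, immediate early genes, hypoxia and glycolysis, collagen and matrix, autophagy and aggresome, proteasome, cytosolic ribosomal proteins, and markers of leukocytes, endothelium, fibroblasts and erythroid cells. The named genes followed a rule fixed before the data were examined: HDAC6, ARID1A and 1 further gene, which is not reported here, always, then called genes, and where fewer than 5 were called in a direction up to 10 genes with an Entrez ID by the smallest of their 3 folds, as values only. For single interventions the 6 largest folds each way were named, for the other pairs 5 each way, and up to 4 members per list. Other genes, named to show list members or near-identical partners, were chosen after their values were seen.

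The alternatives were another normalization (DESeq2 size factors, total count only), DESeq2 1.42.0 and limma-voom as tests, other filters, prior counts, thresholds and floors, no covariate, histone genes left out of library sizes, and each library left out in turn. The authors' FPKM, exchanged controls, the removal of genes high in the vehicle library and small noncoding RNA genes left out of library sizes were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.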

Results

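The transcriptome of TOV21G cells, a human ovarian clear cell carcinoma line, was sequenced after interference with HDAC6, a mainly cytoplasmic deacetylase that acts on tubulin among other proteins. The title of the series ties HDAC6 activity to ovarian cancers with mutations in ARID1A, a subunit of the SWI/SNF chromatin remodelling complex. HDAC6 was targeted with a short hairpin RNA (shHDAC6) or with the small-molecule HDAC6 inhibitors ACY1215 and CAY10603. The controls were a control hairpin (shControl) and the drug vehicle. Each of the 5 treatments has 1 library, with total counts between 43498805 (vehicle) and 57442767 (shControl). A count was recorded for 18571 genes in shControl, 18719 in shHDAC6, 22189 in vehicle, 21031 in ACY1215 and 21265 in CAY10603. Doses, times and the hairpin used for this library are not given in the sources used here.

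The HDAC6 transcript (Entrez 10013) was lower in the library labelled shHDAC6 than in shControl, at 29.2 CPM (95% interval 27.8 to 30.7) against 48.0 CPM (46.2 to 49.8), a log2 fold of -0.72. It was also lower in the ACY1215 library, at 33.2 CPM (31.6 to 34.8) against 51.1 CPM (49.0 to 53.2) in vehicle, a log2 fold of -0.62. In the CAY10603 library it stood at 48.2 CPM (46.3 to 50.2), a log2 fold of -0.08. Inhibitors act on the protein, so the transcript does not measure their effect. In the pooled fit HDAC6 had a log2 fold of -0.50 with a standard error of 0.21 (edgeR adjusted p = 1.00), which ranged from -0.72 without vehicle to -0.33 without shControl or without shHDAC6.

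**Figure D1:**
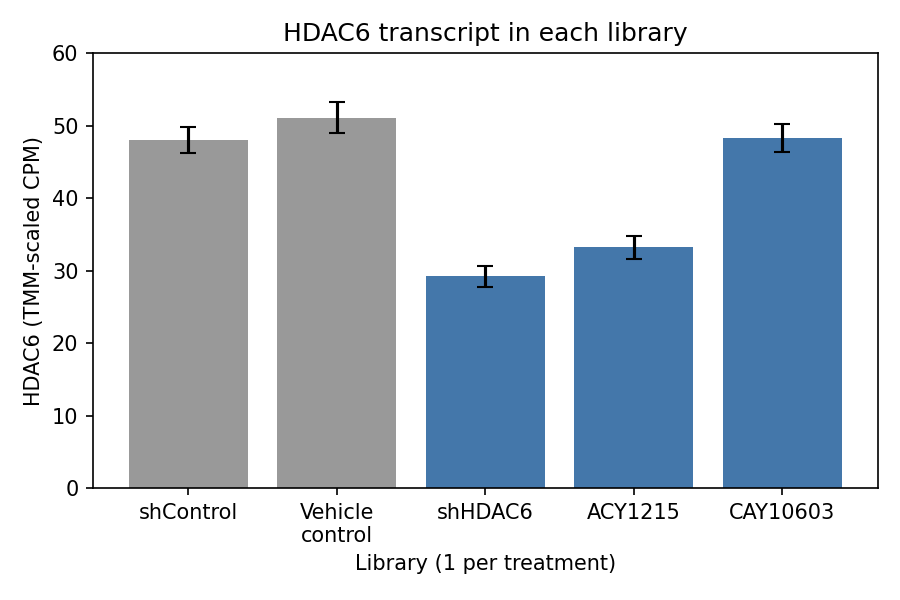
HDAC6 transcript level in TMM-scaled CPM (vertical axis, from 0) in each of the 5 libraries, with controls in grey and interventions in blue; error bars are exact 95% Poisson intervals for counting error. The shHDAC6 library (29.2 CPM) and the ACY1215 library (33.2 CPM) lie below the other 3 libraries.

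The first comparison asked which transcripts moved with repressed HDAC6 over all 3 interventions, each set against its own control. Few genes moved the same way in all of them. Among 10741 genes, 2403 (22.4%) had the same sign of fold in the 3 interventions, against 33.4% for a knockdown sign unrelated to the drug signs, and VGF alone was at least 1.5-fold apart from its control in all 3, on the higher side. VGF, a secreted neuroendocrine protein, had log2 folds of 0.67, 3.44 and 0.86 for shHDAC6, ACY1215 and CAY10603. It stood at 29.5 CPM in ACY1215 but at 1.35 in shControl, 2.18 in shHDAC6, 2.69 in vehicle and 4.93 in CAY10603. The counting intervals of its log2 folds began at 0.26 for shHDAC6 and 0.55 for CAY10603, both below 1.5-fold. Counting error therefore leaves open whether VGF reached 1.5-fold in either of these pairs. SGK3, a kinase related to AKT, had folds of 0.42, 1.62 and 0.89, and FZD5, a Wnt receptor, of 0.35, 0.53 and 0.35. Further genes on the higher side by the smallest of the 3 folds were the small RNAs SCARNA10 (2.12, 0.88 and 0.48), SNORA79 and RMRP, and PLEKHM3, FIBCD1, LPCAT2 and HLA-H, the last a pseudogene that shares sequence with other class I genes. On the lower side, FNTB, the beta subunit of farnesyltransferase, had folds of -0.41, -0.65 and -0.44, C1orf63 of -0.53, -0.41 and -0.43, and the placental hormone INSL4 of -0.50, -0.45 and -0.52. CCDC28B, SNORD116-13 and LOC729732 were lower in all 3 as well, as were NSFP1, DHRS4L2, KGFLP2 and GUSBP4, which have near-identical relatives, so that reads can be split between copies. Of the 10 genes named on each side, 8 on the higher side lay above both controls in all 3 interventions and 7 on the lower side lay below both. The exceptions were VGF, SGK3, DHRS4L2, LOC729732 and SNORD116-13, whose common sign turned with the control. ARID1A had folds of 0.35, -0.05 and 0.14.

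At an adjusted p under 0.05, 0 of 13449 genes passed the edgeR quasi-likelihood test, and 0 passed DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 100 genes by edgeR (50 higher and 50 lower), against 672 expected by chance, 112 by DESeq2 and 121 by limma-voom. Differences between the 3 interventions count as spread in this fit. Without control replicate 2 (the vehicle) 3 genes were called, which are rows with 0 counts in shHDAC6: GTF2IP1, BC007880 and CR749695. Without repressed HDAC6 replicate 2 (ACY1215) 5 were called: EIF3CL, LOC100505876, BC017214, HIST2H3C and DKFZp547E087, all 8 named after their values were seen.

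Of 26 gene lists tested with camera, 4 passed at the preset correlation and 0 passed with an estimated correlation. No member of any list passed the gene test, and the count was also 0 adjusted over the list alone. Hypoxia and glycolysis genes ranked above the other genes (25 genes, median pooled log2 fold 0.23, camera adjusted p = 8.2e-06), with medians of -0.09, 0.67 and 0.19 for shHDAC6, ACY1215 and CAY10603. Of the 25 members 17 were lower in shHDAC6 than in shControl, while against vehicle the shHDAC6 median was 0.30. Examples are lactate dehydrogenase A, LDHA (-0.09, 1.03 and 0.49), and the glucose transporter SLC2A1 (0.14, 0.78 and 0.27). Collagen and matrix genes also ranked higher (25 genes, median 0.17, camera adjusted p = 7.8e-04), with medians of -0.00, 0.62 and 0.16 and 12 of 25 members higher in shHDAC6. THBS1, thrombospondin 1, had -1.40, 1.25 and 0.28, and COL5A2 had 0.38, 1.03 and 0.51. Cytosolic ribosomal protein genes ranked higher (71 genes, median 0.05, camera adjusted p = 0.029) although their shHDAC6 median was -0.17. G2 and M phase genes ranked lower (30 genes, median -0.12, camera adjusted p = 0.029), while their shHDAC6 median was 0.49 and their ACY1215 median -1.29. The estimated correlation between list genes was 0.98 for G2 and M phase, 0.90 for hypoxia, 0.57 for ribosomal protein and 0.26 for matrix genes. With it the camera adjusted p was 0.97 for each of the 4 lists, and limma-voom ended the G2 and M phase call (camera adjusted p = 0.064). Leaving out ACY1215 reversed the G2 and M phase rank (adjusted p = 6.1e-11) and the ribosomal one (adjusted p = 0.55), and ended the hypoxia and matrix calls (adjusted p = 0.44 and 0.35). Leaving out vehicle, which leaves only the shRNA pair as a contrast, reversed all 4, with adjusted p = 3.3e-04 for G2 and M phase, 2.8e-04 for ribosomal protein, 0.39 for hypoxia and 1.00 for matrix genes.

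**Figure D2:**
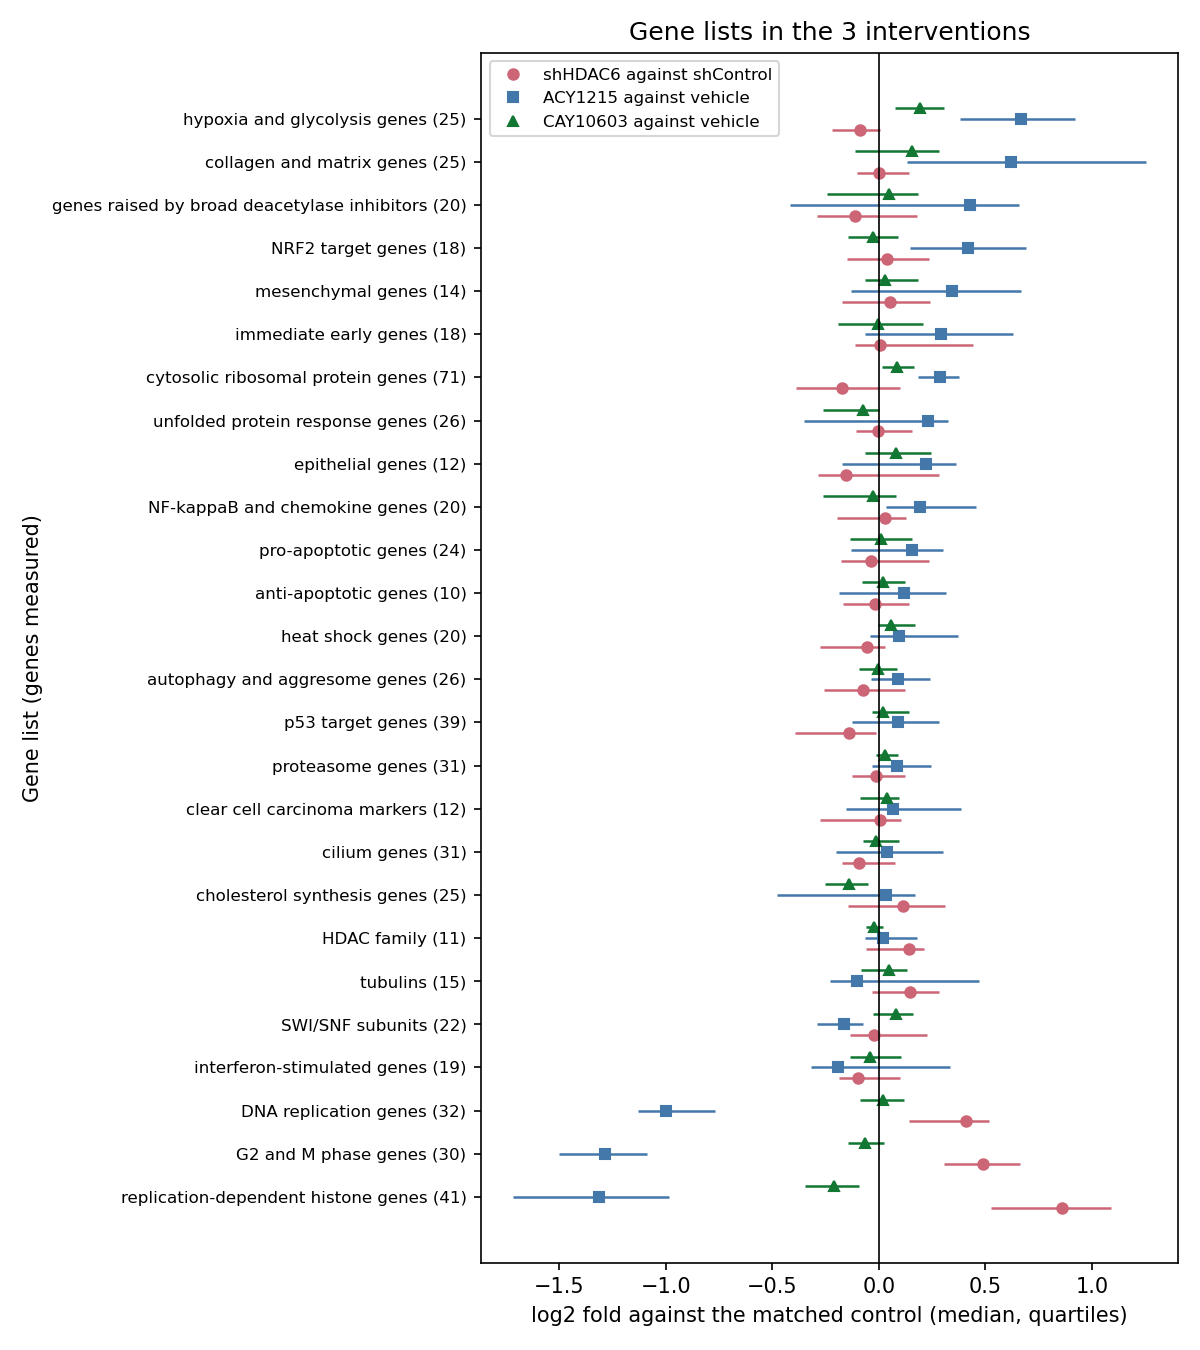
Median log2 fold against the matched control (horizontal axis) for each of the 26 gene lists with at least 5 measured members (vertical axis, number of genes in brackets); points are medians and lines span the quartiles over genes of 1 library pair, for shHDAC6 (circles), ACY1215 (squares) and CAY10603 (triangles). The ACY1215 medians of the histone, G2 and M phase and DNA replication lists lie at -1.31, -1.29 and -0.997, where those of shHDAC6 lie at 0.86, 0.49 and 0.41.

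Knockdown was described by the shHDAC6 and shControl libraries, in which 74 of 10741 genes differed at least 2-fold, 47 higher and 27 lower in shHDAC6. Cell cycle transcripts were higher in the shHDAC6 library. All 30 G2 and M phase genes were higher (median log2 fold 0.49, percentile 100 among random lists), among them KIF20A, a mitotic kinesin (0.70), and AURKB, aurora kinase B (0.72). Of 32 DNA replication genes 30 were higher (median 0.41, percentile 100), and of 41 replication-dependent histone genes 40 were higher (median 0.86, percentile 100), 14 of them at least 2-fold. Of 39 p53 target genes only 9 were higher (median -0.14, percentile 0.80), with MDM2, the ubiquitin ligase of p53, at -0.68. The 2 control libraries differed in the same lists. In shControl the G2 and M phase median lay below vehicle (log2 fold -0.53) and the p53 target median above it (log2 fold 0.45). Against vehicle the shHDAC6 library had a G2 and M phase median of -0.08 and a p53 target median of 0.33, both of the opposite sign. Its DNA replication median against vehicle was 0.13 and its histone median 0.18, both smaller than against shControl.

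The largest single folds in the shHDAC6 library were mostly of small or read-through RNAs. U6, a spliceosomal RNA, had a log2 fold of 3.62 (counting interval 3.38 to 3.92), SCARNA10 of 2.12, SNORD17 of 1.98 and the signal recognition particle RNA row, Metazoa_SRP, of 1.94. The read-through rows SLMO2-ATP5E (3.27) and PHOSPHO2-KLHL23 (2.55) overlap their single-gene rows, and ATP5E had -1.07, so the split of reads is uncertain. On the lower side GTF2IP1, a pseudogene near-identical to GTF2I, had 0 counts in shHDAC6 and 4480 in shControl, at least 1367-fold lower, while GTF2I had 0.14. GTF2IP1 stood at 77.8 CPM in shControl, and GTF2I at 507 CPM in shControl and 560 CPM in shHDAC6. Reads can be split between these copies, so the 0 may not mean absent expression. The clone rows BC007880 and CR749695 also had 0 counts in shHDAC6, at least 247-fold and at least 218-fold lower. ZBED2 (-1.89), SCARNA9L (-1.62) and IRF9, a transcription factor of interferon signalling (-1.76), completed the list. For IRF9 the authors' FPKM fell less, from 7.27 in shControl to 3.84 in shHDAC6, than the counts (688 and 185), so the size of its fall is uncertain. With the vehicle in place of shControl, 128 genes differed at least 2-fold, 31 higher and 97 lower in shHDAC6.

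ACY1215 against vehicle gave the largest count of the 3 interventions, 505 of 10741 genes at least 2-fold, 179 higher and 326 lower in the ACY1215 library. Cell cycle transcripts were lower. All 30 G2 and M phase genes were lower (median log2 fold -1.29, percentile 0), 27 of them at least 2-fold, among them KIF20A (-1.81), KIF2C (-1.75), CCNA2, cyclin A2 (-1.62), and AURKB (-1.58). Of 32 DNA replication genes 31 were lower (median -0.997, percentile 0), with RRM2, a ribonucleotide reductase subunit, at -1.44. Of 41 replication-dependent histone genes 40 were lower (median -1.31, percentile 0), 30 of them at least 2-fold. Histone genes have near-identical copies, so values of single ones are uncertain. All 25 hypoxia and glycolysis genes were higher (median 0.67, percentile 100), with LDHA at 1.03 and EGLN3, an oxygen-sensing prolyl hydroxylase, at 1.80. Of 25 collagen and matrix genes 20 were higher (median 0.62, percentile 100), with COL5A1 at 1.73 and COL5A2 at 1.03. Fibroblast markers, which include collagen genes of the matrix list, summed to 38.5 CPM in ACY1215 and 28.8 CPM in vehicle. NRF2 targets were higher in 15 of 18 (median 0.42), among them NQO1 (0.67) and HMOX1, heme oxygenase 1 (1.14), and 70 of 71 ribosomal protein genes were higher (median 0.29, percentile 100).

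The largest folds in the ACY1215 library were those of VGF (log2 fold 3.44, counting interval 3.19 to 3.74), MAP1B, a microtubule-associated protein (3.03), FEZ1, an adaptor of axonal transport (2.50), PLAUR, the urokinase receptor (2.45), STEAP3, a metalloreductase (2.44), and the receptor kinase EPHB2 (2.38). The largest on the lower side were the histone genes HIST1H2BO (-2.10), HIST1H2BL (-2.01), HIST1H2BJ (-1.96) and HIST1H3H (-1.92), with UGT8 (-1.96) and TROAP, a spindle protein (-1.87). UGT8 was also 18.2 CPM in vehicle against 0.64 CPM in shControl. With shControl in place of vehicle the count was 323 genes, 196 higher and 127 lower. The medians were then -0.76 for G2 and M phase, -0.70 for DNA replication and -0.70 for histone genes. They were 0.35 for hypoxia and glycolysis, 0.31 for matrix, 0.56 for NRF2 target and 0.35 for ribosomal protein genes.

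CAY10603 against vehicle gave 29 genes at least 2-fold apart, 3 higher and 26 lower in the CAY10603 library. G2 and M phase genes lay near vehicle (median log2 fold -0.07, 11 of 30 higher), as did DNA replication genes (median 0.02, 18 of 32 higher). Histone genes were lower in 35 of 41 (median -0.21, percentile 0). Hypoxia and glycolysis genes were higher in 23 of 25 (median 0.19, percentile 100) and matrix genes in 16 of 25 (median 0.16), with fibroblast markers at 37.9 CPM against 28.8 CPM in vehicle. Cholesterol synthesis genes were higher in 4 of 25 (median -0.14, percentile 0.010), among them EBP (-0.43) and INSIG1 (-0.39). The largest higher folds were HIST2H3C (1.11), LOC100288142 (1.05), CDKN2A, a cyclin-dependent kinase inhibitor (1.01), ZBED2 (0.93), SGK3 (0.89) and TERC, the telomerase RNA (0.86). CDKN2A stood at 3.57 CPM in vehicle, 7.40 in shControl and 7.22 in CAY10603. ZBED2 and SGK3 were higher in shControl than in vehicle too. The largest lower folds were all of pseudogene or clone rows, AK298300 (-1.74), LOC646214 (-1.57), AK311113 (-1.56), AK123584 (-1.50), BC070495 (-1.45) and AK123889 (-1.45). These 6 transcripts were high in vehicle and low in both shRNA libraries, as AK311113 shows with 141 CPM in vehicle, 6.08 in shControl and 8.71 in shHDAC6. Of the 26 lower genes 25 were at least 2 times higher in vehicle than in both shRNA libraries, and without such genes the count was 4. With shControl in place of vehicle it was 120, 92 higher and 28 lower, and the CAY10603 medians turned to 0.43 for histone, 0.48 for G2 and M phase, -0.25 for hypoxia and glycolysis and -0.08 for matrix genes.

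Whether the interventions moved the same genes was asked across 10741 genes, which are not independent replicates, so no p is given. The folds of shHDAC6 and ACY1215 share no library and had a Pearson correlation of -0.31 (Spearman -0.32), with the same sign in 38.7% of genes. At 2-fold or more 25 genes moved in opposite directions, against 1.88 for independent lists, and 1 moved the same way. For shHDAC6 and CAY10603 the correlation was -0.23 (Spearman -0.30). The 2 drugs share the vehicle library and had a correlation of 0.49 (Spearman 0.47), against 0.54 simulated for unchanged libraries with counting error and 0.50 with the fitted dispersion. Their covariance was 0.0407, against 0.00219 and 0.0720 in these simulations. The fitted dispersion comes from the pooled fit, where differences between interventions count as spread. It can therefore overstate the spread of unchanged libraries. Both drugs were at least 2-fold lower for 25 genes, against 0.79 for independent lists and 5.70 simulated at the fitted dispersion, and both were at least 2-fold higher for 1 gene, against 0.05 and 14.9. All 25 shared lower genes were at least 2 times higher in vehicle than in both shRNA libraries. Part of that overlap may be set by the shared vehicle library, which cannot be split. With the mean of both controls for every intervention the correlations were -0.11, -0.15 and 0.20. The values simulated for unchanged libraries at the fitted dispersion were 0.34, 0.34 and 0.33. That simulation held no difference between the controls, which enters the knockdown and drug folds with opposite signs. The gap to the simulated values can therefore not be read as opposition of the interventions.

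**Figure D3:**
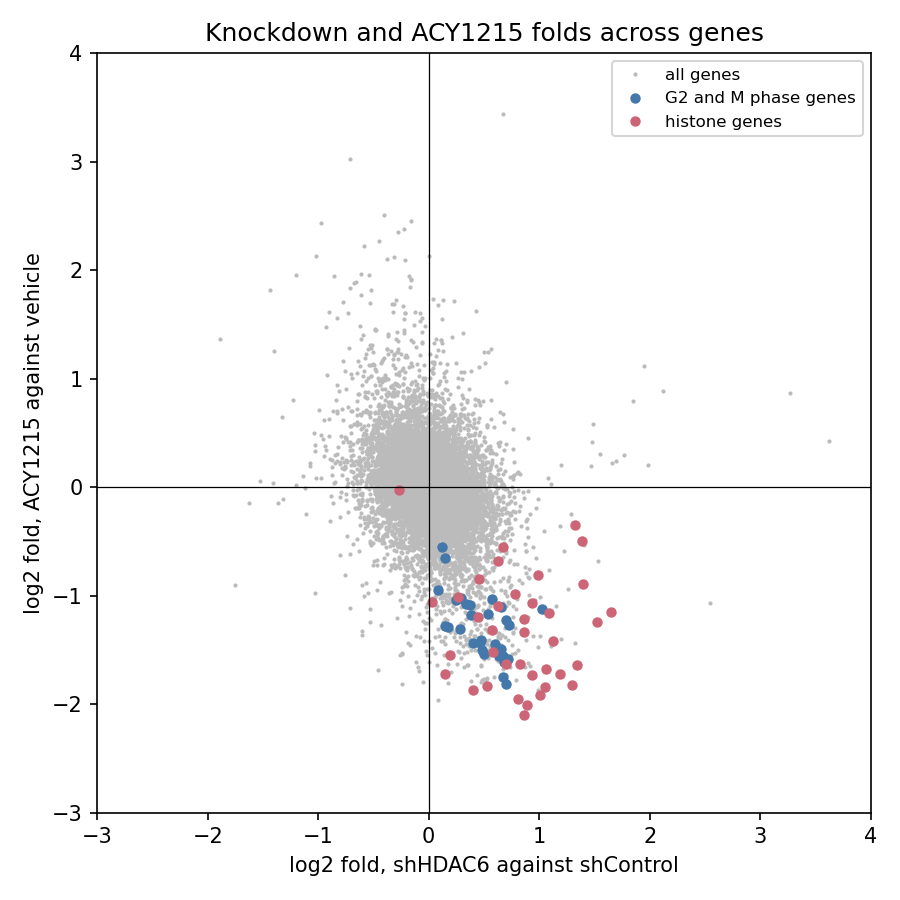
Log2 folds of shHDAC6 against shControl (horizontal axis) and of ACY1215 against vehicle (vertical axis) for genes with a mean of at least 5 CPM, 1 grey point per gene, with G2 and M phase genes in blue and histone genes in red; 3 genes with 0 counts in shHDAC6 lie outside the axes. The blue and most red points lie to the right of 0 and below 0, and the Pearson correlation across genes is -0.31.

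The HDAC6 inhibitors were set side by side without known doses or times. Between the CAY10603 and ACY1215 libraries 352 genes differed at least 2-fold, 241 higher and 111 lower in CAY10603. All 30 G2 and M phase genes were higher in CAY10603 (median log2 fold 1.26), 26 of them at least 2-fold, as were 31 of 32 DNA replication genes (median 1.02). The largest higher folds were HIST1H2BO (1.91), HIST1H2BF (1.80), FBXO5, an inhibitor of the anaphase-promoting complex (1.77), NCAPH, a condensin subunit (1.73), and HMGB2 (1.71). The largest lower ones were MAP1B (-2.78), VGF (-2.57), PPP2R2C (-2.33), STEAP3 (-2.22) and CLGN, a chaperone of the endoplasmic reticulum (-2.21). All 25 hypoxia and glycolysis genes were lower in CAY10603 (median -0.48). With 1 library each the difference between the compounds has no replicate check.

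The 2 controls served as a yardstick, since neither had an HDAC6 intervention. They come from different experiments (shRNA and drug), so their difference also holds that between the experiments. The pairs of an intervention with its own control do not hold it, so the counts below are not a background level for them. Between shControl and vehicle 152 genes differed at least 2-fold, 55 higher and 97 lower in shControl, more than for shHDAC6 (74) or CAY10603 (29) and fewer than for ACY1215 (505). Of 39 p53 target genes 35 were higher in shControl (median log2 fold 0.45, percentile 100), with MDM2 at 1.22 and CDKN1A, the cell cycle inhibitor p21, at 1.10. All 30 G2 and M phase genes were lower in shControl (median -0.53, percentile 0). Hypoxia and glycolysis genes were higher in 22 of 25 (median 0.44, percentile 100). The largest higher folds were ZBED2 (2.03), SGK3 (1.75), PRODH, a mitochondrial proline dehydrogenase (1.72), KIAA1653 (1.72) and THBS1 (1.68). The largest lower folds were ESRG (-7.20), REXO1L1 (-6.17), UGT8 (-4.74), AK298300 (-4.71) and BC042616 (-4.68). These 5 transcripts were higher in vehicle than in each of the other 4 libraries.

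The remaining lists are given by their medians. In the order shHDAC6, ACY1215 and CAY10603, the medians were 0.14, 0.02 and -0.02 for the HDAC family, -0.03, -0.16 and 0.08 for SWI/SNF subunits, -0.04, 0.16 and 0.01 for pro-apoptotic genes, and -0.02, 0.12 and 0.02 for anti-apoptotic genes. They were -0.05, 0.09 and 0.06 for heat shock genes, -0.00, 0.23 and -0.07 for unfolded protein response genes, 0.15, -0.10 and 0.05 for tubulins, -0.09, 0.04 and -0.01 for cilium genes, and -0.07, 0.09 and -0.01 for autophagy and aggresome genes. Genes raised by broad deacetylase inhibitors had -0.11, 0.43 and 0.05, epithelial genes -0.16, 0.22 and 0.08, mesenchymal genes 0.05, 0.34 and 0.03, clear cell carcinoma markers 0.01, 0.07 and 0.04, and proteasome genes -0.01, 0.09 and 0.03. Interferon-stimulated genes had -0.10, -0.19 and -0.04, NF-kappaB and chemokine genes 0.03, 0.19 and -0.03, and immediate early genes 0.01, 0.29 and -0.00. In the ACY1215 library the percentile among random lists was 100 for genes raised by broad deacetylase inhibitors (12 of 20 higher), 99.8 for immediate early, 99.7 for mesenchymal, 99.2 for unfolded protein response and 1.32 for SWI/SNF genes. For CAY10603 the unfolded protein response percentile was at the other end, 0.09 (7 of 26 higher). For shHDAC6 the tubulin percentile was 98.9 (11 of 15 higher). With the other control, 15 of the 26 list medians changed sign for shHDAC6, 5 for ACY1215 and 17 for CAY10603. For ACY1215 these were p53 target (0.09 to -0.35), epithelial (0.22 to -0.28), heat shock (0.09 to -0.08), broad deacetylase inhibitor (0.43 to -0.03) and interferon-stimulated genes (-0.19 to 0.01). Markers of other cell types were low in all libraries, with summed levels of 7.06 to 9.25 CPM for leukocytes, 0.84 to 1.82 for endothelium, 0.21 to 0.53 for erythroid cells, and 25.8 to 38.5 for fibroblasts, mostly COL1A2.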

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

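The tests on the shControl library and the exchanged control below were chosen only after the result was seen, and the others before. Groups of 4 or more samples are absent, so no library could be tested as lying far from its group. The replication-dependent histone genes stood out because, each against its own control, the knockdown library lay on one side and both drug libraries on the other. Their median log2 fold was 0.86 in shHDAC6 against shControl, -1.31 in ACY1215 against vehicle and -0.21 in CAY10603 against vehicle. With the other control the medians were 0.18, -0.70 and 0.43, so the direction of CAY10603 turned and the knockdown median was smaller. This difference between the shRNA and drug experiments was not tested, with 1 library per treatment, and 1 of 26 lists met the criterion of medians of at least 0.1 in size.

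Knockdown and ACY1215 were opposed across genes too, and the Pearson correlation of -0.31 stayed at -0.31 with gene length and expression trends removed, at -0.31 without the genes high in vehicle, at -0.28 without the listed cell cycle and histone genes and at -0.39 without read-through, pseudogene, LOC and clone entries over 20 CPM, values that argue against each of the 4 as the whole source. A hypothesis that stays open is a low cell cycle level in the shControl library, since shHDAC6 had a G2 and M phase median of -0.0801 against vehicle while shControl had -0.53. The hypothesis was found in the same data, and how far it reaches beyond the listed genes was not tested, as unlisted cell cycle genes such as FOXM1 (0.59 and -1.75) stayed among the genes behind the value of -0.28. An effect of HDAC6 knockdown on these genes stays open as well, untested with 1 library per hairpin.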

How the results depend on the processing

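The authors' FPKM, exchanged controls, the removal of genes high in vehicle, and small noncoding RNA genes left out of library sizes were chosen after seeing the data. The count of genes called for repressed HDAC6 against control was 0 in every setting except single libraries left out, where it ranged from 0 to 5; by edgeR, DESeq2, limma-voom and limma on FPKM, between 67 and 267 genes lay under an unadjusted p of 0.05. List calls numbered 4, against 7 with no experiment type covariate, 3 with limma-voom (G2 and M phase adjusted p = 0.064), 0 with the correlation estimated per list and 4 to 8 with single libraries left out. With libraries left out, the adjusted p ranged from 6.1e-11 to 3.3e-04 for G2 and M phase, 1.0e-11 to 0.44 for hypoxia and glycolysis, 8.5e-06 to 1.00 for collagen and matrix and 1.1e-09 to 0.55 for ribosomal protein genes, and directions reversed without vehicle (all 4) or without ACY1215 (G2 and M phase, ribosomal). In these fits a lone library is assumed to vary like the others. The cause of these shifts was not tested. No paired analysis was possible because no replicate number pairs the libraries, although the experiment type term set each intervention against the control of its own experiment.

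The 2-fold counts for shHDAC6, ACY1215, CAY10603, CAY10603 against ACY1215, and shControl against vehicle depended on the floor and threshold, by construction. They were 260, 932, 92, 706 and 494 at a mean CPM of at least 1, 40, 270, 17, 179 and 67 at 20, and 539, 1463, 112, 1115 and 723 at 1.5-fold. Exchanging controls gave 128 for shHDAC6, 323 for ACY1215 and 120 for CAY10603, and CAY10603 without vehicle-high genes gave 4, a removal that takes out genes chosen for being high in vehicle. Other prior counts and scalings kept each count within 1.5 times.

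The correlations kept their sign in all settings. In the order shHDAC6 with ACY1215, shHDAC6 with CAY10603, and the 2 drugs, they were -0.11, -0.15 and 0.20 with the mean of both controls, which share that mean and gave 0.34, 0.34 and 0.33 in simulated unchanged libraries. The simulated libraries held no difference between the controls, so the gap cannot be read as an effect of the interventions. At a mean CPM of at least 20 the first was -0.35 and the third 0.51, by Spearman the second was -0.30 and the third 0.47, and without vehicle-high genes the third was 0.45. HDAC6 in ACY1215 was -0.72 with total count only, a scaling that moved the median of all genes by -0.10 in that pair. The p53 target median in ACY1215 became -0.0143 with total count only. Of 520 list medians under other prior counts and scalings 513 stayed within the 95% interval of the median over the list genes. Under the same settings 218 of 224 single-pair gene folds moved by less than their counting interval. Exchanged controls are not among these settings. With them 15 of 26 list medians changed sign for shHDAC6, 5 for ACY1215 and 17 for CAY10603.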

Other observations

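The tests of depth, of a fixed ratio of genomic DNA, of transduction, of scaling and of the recovery of all short RNAs were chosen only after the result was seen. Values of some genes tied to cell death and metabolism follow in the order shHDAC6, ACY1215 and CAY10603, each against its own control, with no call by edgeR. PMAIP1, which encodes the pro-apoptotic protein NOXA, had log2 folds of -0.31, -0.74 and -0.39, and its level in vehicle (25.7 CPM) exceeded that in shControl (14.8 CPM), so that both drug libraries lay above shControl. BBC3, which encodes PUMA, had -0.38, -0.37 and -0.04. These 2 genes do not stand for their class, as of 24 pro-apoptotic genes 4 were higher and 3 lower in all 3 interventions. TXNIP, an inhibitor of thioredoxin, had 0.59, 0.55 and 0.24, with -0.76 between shControl and vehicle. The alpha tubulin TUBA1A had 0.32, 0.73 and 0.47, with 0.92 between the controls, so that both drug libraries lay below shControl. The heat shock protein of the endoplasmic reticulum HSPA5 had 0.05, 0.71 and 0.24, with 0.41 between the controls, while the stress-induced transcription factor DDIT3 had 0.13, -1.42 and -0.87, with -1.20 between the controls.

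Olfactory receptor genes, usually silent outside the nose, differed between libraries, and 375 of them summed to 13.8 CPM in vehicle, 6.17 in CAY10603, 4.47 in ACY1215, 0.95 in shHDAC6 and 0.87 in shControl, with 208 of them detected in vehicle and 9 in shControl. The vehicle library had the lowest total of the 5, 0.757 times that of shControl, which argues against depth. An admixture of genomic DNA at a fixed ratio stays open. Expression of their own would lift genes from the olfactory receptor ratio of CAY10603 to vehicle (0.446) towards 1. Of 278 vehicle-high genes 2.16% had a 99% counting interval below that of the olfactory receptor genes. For 130 (46.8%) the interval did not overlap that of the olfactory receptor genes, and the median ratio of the 278 genes was 0.724. A fixed ratio thus needs expression of their own in many of these genes, which was not tested. A ratio above 1 was found for 58, 6 of them with a 99% counting interval above 1. In genes with no count in either shRNA library the count rose with transcript length in vehicle (Spearman 0.61), ACY1215 (0.51) and CAY10603 (0.53). Only 59.3% of these genes had a length, so the check is void and reads spread over silent genes stay open. Transduction and selection stays open too, because it is confounded with the shRNA experiment, where the lowest drug-experiment level was 4.70 times the highest shRNA level, although it would leave the difference among the 3 drug-experiment libraries.

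Several structured RNAs were higher in all 3 interventions. Metazoa_SRP had log2 folds of 1.94, 1.11 and 0.41, RPPH1 of 1.85, 0.79 and 0.30, and RMRP of 1.48, 0.41 and 0.34. With total count only, which moves all folds of a pair by about the same amount, the smallest Metazoa_SRP fold was 0.355. The choice between these scalings thus did not remove the rise, and other errors of scaling were not tested. The medians of 10 C/D box snoRNA genes were -0.28, -0.28 and -0.08, and 7SK was lower in all 3 (-0.54, -0.02 and -0.15). These values argue against a greater recovery of all short RNAs. A recovery that differs between short RNAs was not tested, and SNORD17, itself a C/D box snoRNA, was higher in shHDAC6. Repressed HDAC6 cannot be told apart from a spread between cultures, because 1 library per treatment gives no measure of that spread. The fold of shControl against vehicle was as large as the smallest of the 3 for Metazoa_SRP (-0.53) and RMRP (-0.45) but smaller for RPPH1 (-0.18). That fold also holds the difference between the shRNA and drug experiments, so it does not measure the spread between cultures either.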
